A study of Mus musculus with 8 samples.

How the data were processed

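Total RNA from 8 samples of mouse intestinal organoids was hybridised to Illumina mouse bead arrays, with 1 array per sample. Per the labels, the organoids came from mice on a C57Bl background, carried a mutated Apc and received tamoxifen, after which growth factors were taken out of the medium. Per the labels, 4 samples then received TGF-beta at 3 ng/ml for 18 h and 4 were left untreated. RNA was treated with DNase and checked on a Bioanalyzer, and biotin-labelled cRNA was prepared from it, per the labels' protocols. The labels number the samples 1 to 4 in each group and do not say whether the 4 came from separate cultures or animals. The p-values therefore measure only the spread between these samples, which may be technical apart from the division of the replicates described below.

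The deposited scanner table holds, per the file headers, a non-normalized signal intensity and a detection p-value for each of 45281 probes on each array. The detection p-values move in steps that correspond to 936 negative controls (tolerance 0.01 of a step). The authors' processed value table was deposited without a stated method. From its values it is on a log2 scale and quantile normalized between arrays, with a median of 7.1 in every column. Sorted columns of that deposited log2 table differ by at most 0.01, its lowest value is 6.59, no background subtraction is visible, and each column correlated at 0.998 or more across probes with the log2 intensity of its own array. Scanner software and summarisation are not given in the sources used here. Every column of values was used, with 0 left over. No reads are involved, so the number of arrays limits the precision.

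Normalized values were computed from the signal intensities. Background was corrected with normexp, with the background inferred from the detection p-values, an offset of 16 was added, arrays were quantile normalized and log2 was taken (limma 3.58.1 in R 4.3.3). A probe was tested when its detection p was under 0.05 on at least 4 of the 8 arrays, which left 15573 probes. Gene names came from the platform annotation. It gives 34885 probes a single gene symbol and 18 probes several, and 10378 probes are not listed there and stay unnamed here. The annotation names 13513 of the tested probes with a single symbol. Entrez identifiers of 34807 probes were found in a RefSeq gene table of assembly GRCm38, and 0 symbols needed an update. That table also gave the chromosome of each gene. Its coordinates are not printed because the annotation used here states no genome build. A gene was represented by its tested probe with the highest mean, giving 9062 genes. Of 3154 genes with more than 1 tested probe, 2 had probes past the threshold in opposite directions and 518 had some probes past it and others not.

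The effect of TGF-beta was fitted per probe with limma (lmFit and eBayes, all 8 samples, group alone, two-sided), with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. Differences are log2 values, TGF-beta minus untreated, with the standard error (SE) of the fit. Levels are means with the SD over 4 samples. A probe that was not detected on any array of a group has only a bound there. Its fold is then written as "at least", from the brighter group's mean against a dim-group mean that takes, on each array, the higher of the lowest detected signal and the probe's own signal. Of the genes past the threshold, 56 have such a bound. A gene detected on only some arrays of a group keeps its fold, with the number of arrays beside it, and the size and rank of that fold are less certain.

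Before the data were examined, 36 gene lists with 800 distinct genes were written from textbook knowledge, including markers of other cell types, together with 20 key genes, the tests and most alternatives. Lists with at least 4 tested members, 31 in all, were tested with limma's camera at a preset correlation of 0.01 between genes and adjusted over these lists. A correlation estimated per list was an alternative, and with it the TGF-beta target list and the junction and keratin list kept their calls while 11 others lost them. Where a count adjusted over the list alone is not given beside a list's count, it was the same. fry was run for each list as well. It asks whether a list's genes move on balance in a single direction and does not compare the list with other genes. Of lists that passed camera, the fetal-like and Yap (fry, adjusted p = 0.065), interferon (0.151) and respiratory chain (0.083) lists did not pass fry. The Wnt target (fry, adjusted p = 0.016) and unfolded protein (0.033) lists passed fry but not camera. The genes named are those of a rule fixed beforehand: the 12 largest rises and the 12 largest falls past the threshold whose 4 values in a group do not overlap the other group's, the 20 key genes, and from each list up to 4 members past the threshold with the smallest adjusted p. Bik, Smad3, Sox9, Igfbp4, Phlda1, Apob, Gtse1, Tnfaip3, Lcn2, Hspg2, Gja1, Tgfbi, Cdh1, Id2, Epcam, Gcg, Chga, Muc2 and Dbp lie outside the rule, as do the genes named for differences between replicates and for stratified epithelium, and were chosen after their values were seen.

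The replicate numbers seem to pair the samples. Over the tested probes, the deviations of same-numbered samples from their group means correlated at 0.534, 0.512, 0.514 and 0.554 for replicates 1 to 4. For 8 of 8 arrays the closest match in the other group had the same number. The pairing comes from these values, since the labels tie the numbers to nothing. Much of it is a division into replicates 1 and 4 against replicates 2 and 3. The transcript of Xist, which silences an X chromosome in female cells, was high in replicates 2 and 3 of both groups, and the Y-linked Eif2s3y was high in replicates 1 and 4. Within these sets, the difference of replicate 1 minus 4 correlated at 0.198 between the groups, and that of replicate 2 minus 3 at 0.130. Beyond the division, the 8 matches rest largely on these weak correlations and are not independent, so pairing within a set is uncertain. A fit with the replicate number as a block was planned. A fit with the set as a block, fits within each set, and a fit on set means were added after seeing the data, as was an estimated correlation with the set as a block.

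Other settings fixed beforehand were no background correction, median scaling or cyclic loess in place of quantile normalization, the authors' value table, no filter or a stricter filter (detection p under 0.01 on all 8 arrays), trended and robust variances, array weights, averaging a gene's probes, stricter thresholds, lists without members of other lists, and leaving out each sample in turn. Arrays were compared for signal and detected probes with exact two-sided permutation tests over the 70 assignments of samples to groups, whose smallest possible p is 0.0286.

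The scripts were tested on simulated data for the comparison of TGF-beta with untreated, drawn from the means and spreads of the 15573 probes with 200 of them changed. The fit recovered 1.49% of simulated log2 changes of 0.5, 59.7% of those of 1 and 92.4% of those of 2, with 2 false calls. In the real data 17.7% of probes passed, and the adjustment grows less strict as more probes change, so these rates need not hold there. A simulated shift of -0.50 in the cell cycle list was estimated at -0.47 with 0 of the other lists called, and 0 of 31 lists were called without a change, in simulated probes that vary independently. A simulated log2 difference of 2 between the effects in the sets was recovered for 72.5% of 200 probes, with 4 false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.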

Results

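Gene expression was measured in 8 samples of mouse intestinal organoids, which are epithelial cultures. With intact Apc they grow from crypts into budding, hollow structures and hold stem cells beside absorptive and secretory cells. All samples had Apc, a negative regulator of Wnt signalling and an intestinal tumour suppressor, mutated by tamoxifen. That form and mix of cells need not hold for them. The comparison asks how such epithelium responds to TGF-beta, a cytokine that restrains the growth of normal epithelial cells. There were 4 untreated samples and 4 that received TGF-beta at 3 ng/ml for 18 h. Between 14554 probes (TGF-beta replicate 2) and 16626 probes (untreated replicate 2) were detected above background per array. Untreated arrays detected 16044 ± 668 probes and TGF-beta arrays 15572.5 ± 709 (SD, n = 4 each), a difference that did not pass an exact permutation test (two-sided p = 0.371, adjusted p = 0.400 over 3 measures of signal).

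TGF-beta and untreated samples lay apart on the first principal component of the tested probes, which held 46.9% of the variance. The second component, with 31.6%, separated replicates 1 and 4 from replicates 2 and 3 in both groups. Xist averaged 4.58 in the 4 arrays of replicates 1 and 4 and 9.66 in those of replicates 2 and 3 on the log2 scale, and Eif2s3y averaged 8.35 and 4.58. These sets cross the treatment, with 2 samples of each group in each set. Array correlations within a group ranged from 0.951 to 0.989 across probes. Apc itself gave 5.63 ± 0.16 in untreated and 5.27 ± 0.04 in TGF-beta samples (SD, n = 4), a difference of -0.36 (SE 0.131, adjusted p = 0.087), close to the lowest detected signals of 5.04 to 5.23. No sample with intact Apc was analysed here. Where the probe lies relative to the mutated part is not given in the sources used here, so this value does not check the mutation.

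**Figure D1:**
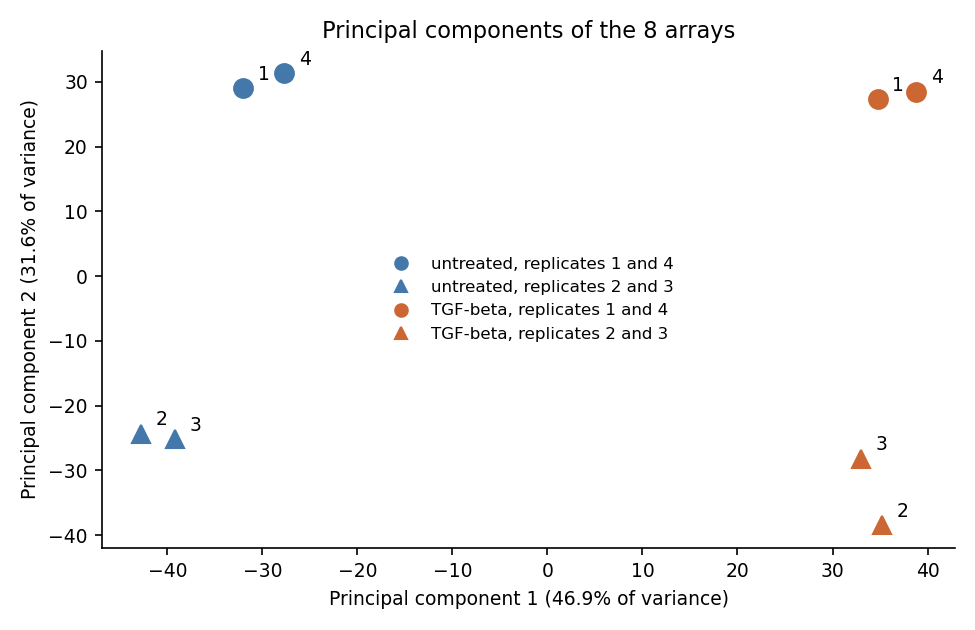
First and second principal components of the 15573 tested probes (percent of variance on each axis), with 1 point per array labelled with its replicate number; colour marks the group and shape the set of replicates. The first component separates the 4 TGF-beta arrays from the 4 untreated arrays, and the second separates replicates 1 and 4 from replicates 2 and 3.

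With TGF-beta, 867 genes rose and 895 fell out of 9062 tested, 19.4% of them, and 429 of the rises and 273 of the falls were at least 2-fold. Over all 8 samples the largest rise was C2cd4a, from 5.68 ± 0.63 to 10.88 ± 0.64 (SD, n = 4; 36.8-fold, adjusted p = 1.7e-05, detected on 3 untreated arrays). It rose by 5.25 in replicates 1 and 4, where Aldh1a3 rose more, and by 5.15 in replicates 2 and 3, where Ctrb1 rose more. Aldh1a3, an enzyme of retinoic acid synthesis, was 33.0-fold higher (adjusted p = 0.00017, 1 untreated array) and P2rx2, an ATP-gated ion channel, 29.9-fold higher (adjusted p = 1.7e-05, 2 untreated arrays). The gut hormone gene Pyy had the smallest adjusted p of these genes, 5.6e-07, and was 27.9-fold higher, from 4.91 ± 0.29 to 9.71 ± 0.21 (1 untreated array). The untreated means of Aldh1a3 (4.95), P2rx2 (4.99) and Pyy lay below the lowest detected signals of the arrays, so the sizes of these folds are uncertain. The other rises were the adaptor Dok2 (at least 14-fold), the caveolar coat gene Cavin3 (19.2-fold), the lipoxygenase Alox12 (16.5-fold, 2 untreated arrays), Clca4a (at least 12.7-fold), the digestive protease precursor Ctrb1 (at least 11.7-fold), Igfbp7 (15.4-fold, 3 untreated arrays), the differentiation keratin Krt20 (14.7-fold) and the small GTPase Rhob (14.4-fold), with adjusted p from 3.2e-06 to 0.0039. Between the sets the size varied most for Ctrb1, at +2.44 in replicates 1 and 4 and +5.54 in replicates 2 and 3, so its rise in replicates 1 and 4 alone was below the pooled bound; Aldh1a3 gave +6.06 and +4.03, Krt20 +4.52 and +3.24, and Dok2 +4.94 and +3.78.

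Over all 8 samples the largest falls were in Clca3b, from 11.19 ± 0.58 to 7.88 ± 1.46 (SD, n = 4; 9.87-fold, adjusted p = 0.0046; -1.73 in replicates 1 and 4 and -4.88 in replicates 2 and 3), and in Rgcc, a regulator of the cell cycle, from 10.40 ± 0.58 to 7.15 ± 0.08 (9.57-fold, adjusted p = 2.8e-05). In replicates 1 and 4 other genes fell more than Clca3b, among them Aqp1 (-3.09) and Rgcc (-2.87). The water channels Aqp1 and Aqp4 were 8.56-fold and 5.29-fold lower, with Aqp4 detected on 3 TGF-beta arrays. Pigr, which carries IgA across the epithelium, was 6.98-fold lower and the antimicrobial lectin Reg3b 5.74-fold lower. Cldn15, a claudin that forms sodium pores between enterocytes, was 5.37-fold lower. Akr1c19 (5.08-fold), Cpn1 (5.03-fold), Bex4 (4.32-fold), the retinaldehyde dehydrogenase Aldh1a1 (4.13-fold, 3 TGF-beta arrays) and the fatty acid transporter Slc27a2 (4.13-fold, 2 TGF-beta arrays) completed the 12, and the adjusted p of these 12 ran from 1.8e-05 to 0.018.

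Of the 1762 genes past the threshold, 1664 had groups that did not overlap; among all tested genes 2250 did not overlap, where chance gives 2.86%. All 1762 had the same sign in replicates 1 and 4 as in replicates 2 and 3, and 1757 moved the same way in all 4 numbered pairs, although these genes were chosen on the pooled samples. Over all 9062 genes, which are not independent replicates, effects in the sets, which share no array, correlated at r = 0.795. Within replicates 1 and 4 alone, 792 genes rose and 798 fell; within replicates 2 and 3 alone, 829 rose and 835 fell. With the replicate number as a block, 1302 genes rose and 1566 fell, including all 1762. Median scaling in place of quantile normalization moved the median of all genes from -0.05 to -0.18 and the split to 495 higher and 941 lower, which took the share of higher genes from 49.2% to 34.5%, and without untreated replicate 1 the lower genes numbered 572.

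**Figure D2:**
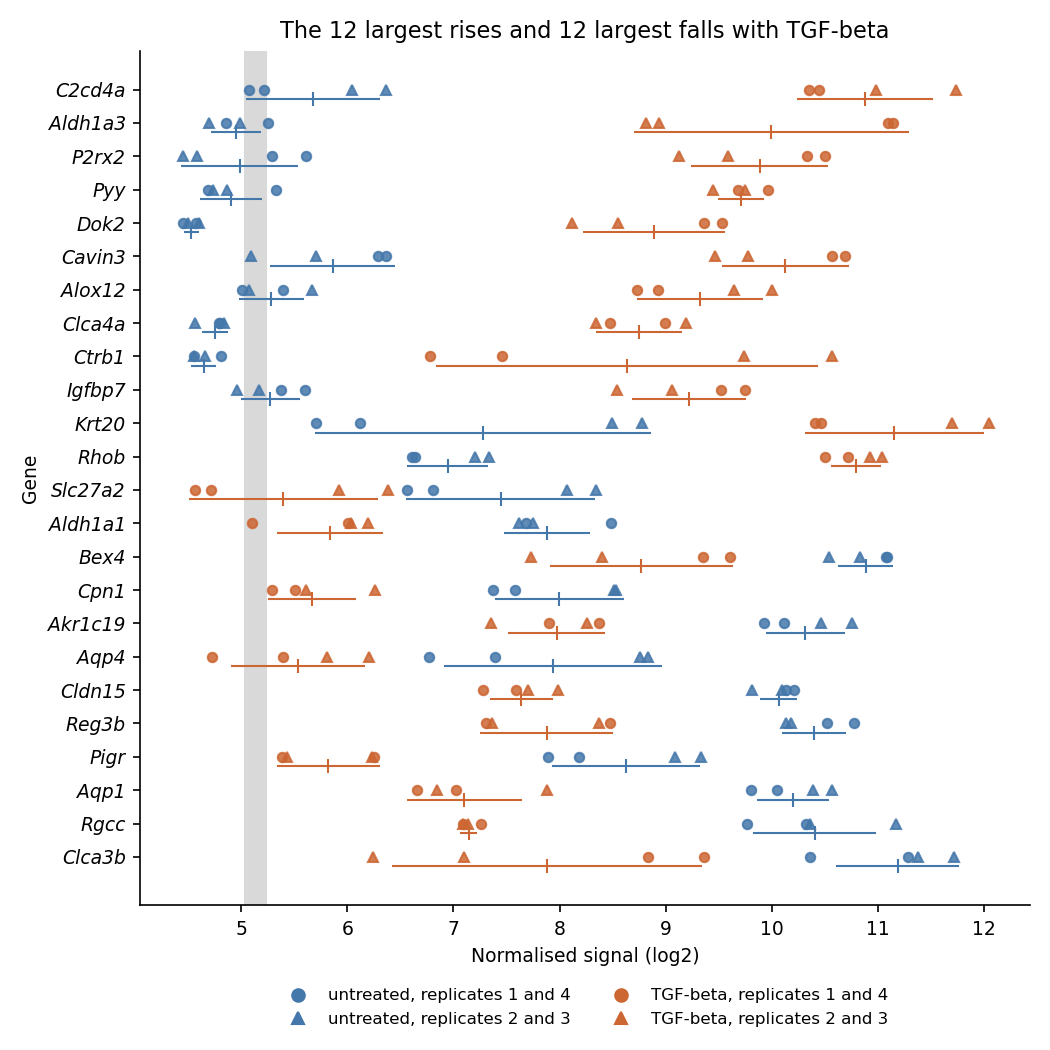
Normalised log2 signal (horizontal axis) of the 12 genes with the largest rises and the 12 with the largest falls, with 1 point per sample, colour for the group and shape for the set of replicates; ticks and lines below the points are group means and SD (n = 4), and the grey band spans the lowest detected signals of the arrays, 5.04 to 5.23. In each gene the 4 values of one group lie apart from the 4 of the other.

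Genes known to be switched on by TGF-beta rose as a group. Of 27 tested members, 20 rose and 0 fell, with 21 rising and 1 falling when adjusted over the list alone and equally at an unadjusted p under 0.05 in limma; the latter was Tgfbi (-1.30, adjusted p = 0.071, and 0.039 with the replicate block). Besides Rhob, Pmepa1, an inhibitor of Smad signalling, rose by 3.55 (SE 0.263, 1 untreated array), the growth factor Pdgfb by 3.17 (SE 0.168) and the Smad repressor Skil by 2.42 (SE 0.149), with adjusted p of 2.3e-05, 3.6e-06 and 1.0e-05. As a whole the list averaged +1.46 (SD over members 1.14), with +1.39 in replicates 1 and 4 and +1.53 in replicates 2 and 3 (camera, adjusted p = 8.4e-16, and adjusted p = 0.0024 with an estimated correlation). Smad7 was below the detection filter. Of 14 tested receptor and Smad genes, 5 rose and 0 fell (limma, 0 falling at an unadjusted p under 0.05): Acvr1 (+1.33), Ski (+1.05), Smad6 (+0.91, 3 untreated arrays), Bmpr2 (+0.82) and Smad3 (+0.58). Smad6 missed the threshold without untreated replicate 1 (adjusted p = 0.051), without background correction (+0.27, 0.060), on the authors' table (+0.29, 0.057) and within replicates 1 and 4 (+0.66, 0.071). The receptors themselves gave +0.38 for Tgfbr1 (SE 0.224, adjusted p = 0.292) and +0.06 for Tgfbr2 (SE 0.207, adjusted p = 0.888). The mean of this list was +0.36 (camera, adjusted p = 0.022, and adjusted p = 0.327 with an estimated correlation). Within replicates 2 and 3 alone, its adjusted p was 0.051. Without the detection filter it was 0.054, and with the stricter filter it was 0.056.

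Genes that promote cell death through the Bcl2 family were higher with TGF-beta. Bcl2l11, which encodes the BH3-only protein Bim, rose from 7.91 ± 0.22 to 9.42 ± 0.58 (SD, n = 4; 2.84-fold, adjusted p = 0.0034), by 0.91 in replicates 1 and 4 and by 2.10 in replicates 2 and 3. Bmf, another BH3-only gene, was not detected in untreated samples and was at least 3.14-fold higher (adjusted p = 0.00096), and Bok was 3.86-fold higher (adjusted p = 5.1e-05). With Pmaip1 (+0.85) and Bik (+0.50), 5 of 9 tested members rose and 0 fell, the same counts as when adjusted over the list alone (limma, 0 falling at an unadjusted p under 0.05; 1 fell with the replicate block). Its members averaged +0.76 (SD over members 0.93), with +0.58 in replicates 1 and 4 and +0.93 in replicates 2 and 3 (camera, adjusted p = 0.0017, and adjusted p = 0.274 with an estimated correlation). Among 4 tested anti-apoptotic members, Bcl2l1 rose (+0.71, adjusted p = 0.023) and the list did not pass (camera, adjusted p = 0.302). Bcl2l1 missed the threshold without untreated replicates 1, 2 or 3 or TGF-beta replicates 3 or 4 (adjusted p from 0.050 to 0.060). Of 19 caspase, death receptor and inhibitor genes, 3 rose and 0 fell (limma; 4 higher and 2 lower at an unadjusted p under 0.05 and adjusted over the list alone, and 5 and 2 with the replicate block): Casp8, the initiator caspase of death receptors (+1.11, adjusted p = 0.00097), Tradd (+0.59) and Dapk2 (+0.48). That list's mean was +0.07 and its median -0.01, and it did not pass (camera, adjusted p = 0.636). Tradd missed the threshold without untreated replicates 1, 3 or 4 or TGF-beta replicates 2, 3 or 4 (adjusted p from 0.050 to 0.069), and Dapk2 without untreated replicates 1, 2 or 4 or TGF-beta replicates 1, 3 or 4 (adjusted p from 0.063 to 0.088).

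Genes of DNA replication and mitosis were lower with TGF-beta. Of 31 tested, 27 fell and 0 rose (limma; 28 lower and 0 higher at an unadjusted p under 0.05 and adjusted over the list alone). The mitotic motor Kif11 was 3.93-fold lower (adjusted p = 0.00019), the replication licensing genes Cdt1 and Mcm5 were 2.97-fold and 2.84-fold lower, and the S-phase regulator E2f1 was 2.19-fold lower. On average the list gave -1.07 (SD over members 0.39), with -0.95 in replicates 1 and 4 and -1.20 in replicates 2 and 3 (camera, adjusted p = 1.0e-15, and adjusted p = 0.301 with an estimated correlation; fry, adjusted p = 0.0021). Mki67 has no named probe here. Of 7 inhibitors of cyclin-dependent kinases, Cdkn2b, a known TGF-beta target, rose 3.16-fold (adjusted p = 0.00036), Cdkn2a was at least 1.23-fold higher, and Cdkn3 (-1.15) and Cdkn2c (-1.14) fell (3 higher and 2 lower adjusted over the list alone; camera, adjusted p = 0.636). Cdkn2a missed the threshold without untreated replicates 1, 2 or 4 or TGF-beta replicates 2, 3 or 4 (adjusted p from 0.061 to 0.088). Cdkn1a gave +0.54 (SE 0.189, adjusted p = 0.075), and its adjusted p was 0.014 with the replicate block and 0.046 without untreated replicate 4. Of 22 Myc and ribosome biogenesis genes, 9 fell and 0 rose (13 lower and 0 higher adjusted over the list alone and at an unadjusted p under 0.05), among them Ncl (-0.91), Rrp12 (-0.80), Odc1 (-0.63) and Ppan (-0.62). Myc gave -0.33 (SE 0.216, adjusted p = 0.346), and the list mean was -0.49 (camera, adjusted p = 7.6e-05, and adjusted p = 0.368 with an estimated correlation).

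Markers of intestinal stem cells were mostly lower with TGF-beta. Of 19 tested, 10 fell and 3 rose (13 and 4 adjusted over the list alone). Lgr5, the receptor that marks crypt base stem cells, fell from 10.62 ± 0.53 to 9.15 ± 0.54 (SD, n = 4; 2.76-fold, adjusted p = 0.0092), and Olfm4 was 5.97-fold lower (adjusted p = 0.018) with groups that overlapped between sets but not within them. Olfm4 missed the threshold without the detection filter and with trended and robust variances. Rgmb (-1.80, 2 TGF-beta arrays), Lrig1 (-1.37), Hopx (-1.15) and Cdca7 (-1.03) also fell, while Phlda1 (+0.70), Sox9 (+0.55) and Igfbp4 (+0.45) rose. Ascl2 gave -0.88 (SE 0.275, adjusted p = 0.052), and its adjusted p was 0.0011 with the replicate block, 0.041 without untreated replicate 4 and 0.027 without TGF-beta replicate 2. Averaged over members the list gave -0.85 (SD over members 0.96), with -0.67 in replicates 1 and 4 and -1.03 in replicates 2 and 3 (camera, adjusted p = 0.0017, and adjusted p = 0.368 with an estimated correlation). With the stricter detection filter, its adjusted p was 0.056.

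Wnt target genes, several of which are also stem cell markers, went both ways. Of 22 tested, 7 fell and 2 rose (11 and 3 adjusted over the list alone, 11 and 5 with the replicate block). Tnfrsf19 (-1.70), Tiam1 (-1.41), Prox1 (-1.33) and the feedback inhibitor Axin2 (-0.72, adjusted p = 0.0034) fell, and Cd44 (+1.19) and Sox9 rose. Over all members the mean was -0.40 (SD over members 0.85) and did not pass (camera, adjusted p = 0.090, and adjusted p = 0.495 with an estimated correlation). It was -0.19 in replicates 1 and 4 and -0.60 in replicates 2 and 3, where it passed (adjusted p = 0.0064), as it did without TGF-beta replicate 4 (adjusted p = 0.046), without the detection filter (0.027), with the stricter filter (0.020) and on set means (0.017). Among 13 Apc and Wnt pathway components, Ctnnb1, which encodes beta-catenin, was higher (+0.76, adjusted p = 0.0046) and the receptor Fzd7 lower (-0.85, adjusted p = 0.014). The mean of that list was -0.02 and its median +0.15, and the list did not pass (camera, upward, adjusted p = 0.833); with the replicate block 1 rose and 2 fell. With median scaling, Ctnnb1 missed the threshold.

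Differentiation markers did not move as groups. Of 18 enterocyte markers, Krt20, Apob (+1.55) and the brush border gene Vil1 (+0.79) rose and the brush border peptidases Dpp4 (-1.41) and Mep1b (-1.17) fell (3 and 3 adjusted over the list alone, 9 and 5 with the replicate block; camera, adjusted p = 0.735). Of 13 goblet cell markers, 0 passed (limma; 1 higher and 3 lower at an unadjusted p under 0.05), with Muc2 at -1.28 (adjusted p = 0.068, and 0.00032 with the replicate block), and the list mean was -0.38 (camera, adjusted p = 0.326). With the replicate block, 6 goblet markers fell and 1 rose and the list passed (camera, adjusted p = 0.029), which it did not with the set block (0.094) or with an estimated correlation (adjusted p = 0.779). Of 11 Paneth cell markers, Pla2g2a fell (-1.01, adjusted p = 0.0093) and 0 rose (limma, 0 at an unadjusted p under 0.05; 1 rose with the replicate block; camera, adjusted p = 0.582). Among 13 enteroendocrine markers, Pyy and the prohormone processing enzyme Cpe (+0.94, adjusted p = 0.0053) rose and 0 fell (limma, 0 at an unadjusted p under 0.05; 1 fell with the replicate block). The hormone gene Gcg gave -0.04 and the granule gene Chga +0.05. The enteroendocrine list had a mean of +0.48 (camera, adjusted p = 0.132), and it passed without untreated replicate 2 (adjusted p = 0.034) and without TGF-beta replicate 4 (adjusted p = 0.026), and on set means (0.049). Of 12 Notch pathway genes, Notch1 fell (-0.72) and Hey1 rose (+0.75, 1 untreated array), with 1 higher and 2 lower adjusted over the list alone and 2 of each with the replicate block (camera, adjusted p = 0.947). Notch1 missed the threshold without untreated replicates 1 or 2 (adjusted p from 0.051 to 0.053), and Hey1 without untreated replicates 1 or 2 or TGF-beta replicates 1 or 2 (adjusted p from 0.067 to 0.074). Hey1 was only +0.21 without background correction (limma, adjusted p = 0.075) and +0.235 on the authors' table (0.074).

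Genes of epithelial junctions and keratins rose. Of 27 tested, 13 rose and 1, Cldn15, fell, the same counts as when adjusted over the list alone. The claudin Cldn4 rose 4.75-fold, and the simple-epithelium keratins Krt19, Krt8 and Krt7 rose 3.11-fold, 2.48-fold and 3.38-fold. The E-cadherin gene Cdh1 gave +0.97 (adjusted p = 0.0019). The Epcam probe was not above background in untreated samples and was at least 1.66-fold higher with TGF-beta. Probe positions were not checked, so this signal does not show that Epcam was silent in untreated samples. The list mean was +0.64 (SD over members 1.11; +0.64 in replicates 1 and 4 and +0.65 in replicates 2 and 3; camera, adjusted p = 5.5e-05, and adjusted p = 0.039 with an estimated correlation).

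Extracellular matrix and integrin genes rose as well, with 15 of 28 higher and 1, Hspg2 (-1.25), lower; adjusted over the list alone, 16 were higher and 2 lower. Fibronectin, Fn1, was not detected in untreated samples and was at least 8.58-fold higher (adjusted p = 6.0e-05). Itgb6, a subunit of an integrin that activates TGF-beta, was 6.0-fold higher, the laminin chain Lamb3 4.63-fold and the collagen-binding Itga2 4.29-fold. The list mean was +1.00 (SD over members 1.07; +0.90 in replicates 1 and 4 and +1.11 in replicates 2 and 3; camera, adjusted p = 6.3e-08, and adjusted p = 0.274 with an estimated correlation, or 0.015 when the set was also a block). Of 22 markers of epithelial-mesenchymal transition, 6 were tested. Fn1 and the membrane protease Mmp14 (+0.96) rose and the intermediate filament gene Vim fell (-1.42), and 3 did not pass. That list's mean of +0.78 passed narrowly (camera, adjusted p = 0.049, and adjusted p = 0.456 with an estimated correlation). Its mean was +0.10 with the stricter detection filter (adjusted p = 0.467), +0.23 without a filter (0.194), +0.35 without background correction (0.073) and +0.38 on the authors' table (0.069), and it missed the threshold with cyclic loess, array weights or averaged probes as well. It also missed it within replicates 2 and 3 (adjusted p = 0.198) and without untreated replicates 1, 3 or 4 or TGF-beta replicates 1 or 2 (adjusted p from 0.057 to 0.083), and Vim missed it without untreated replicate 3 or TGF-beta replicate 3 (adjusted p from 0.057 to 0.063).

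**Figure D3:**
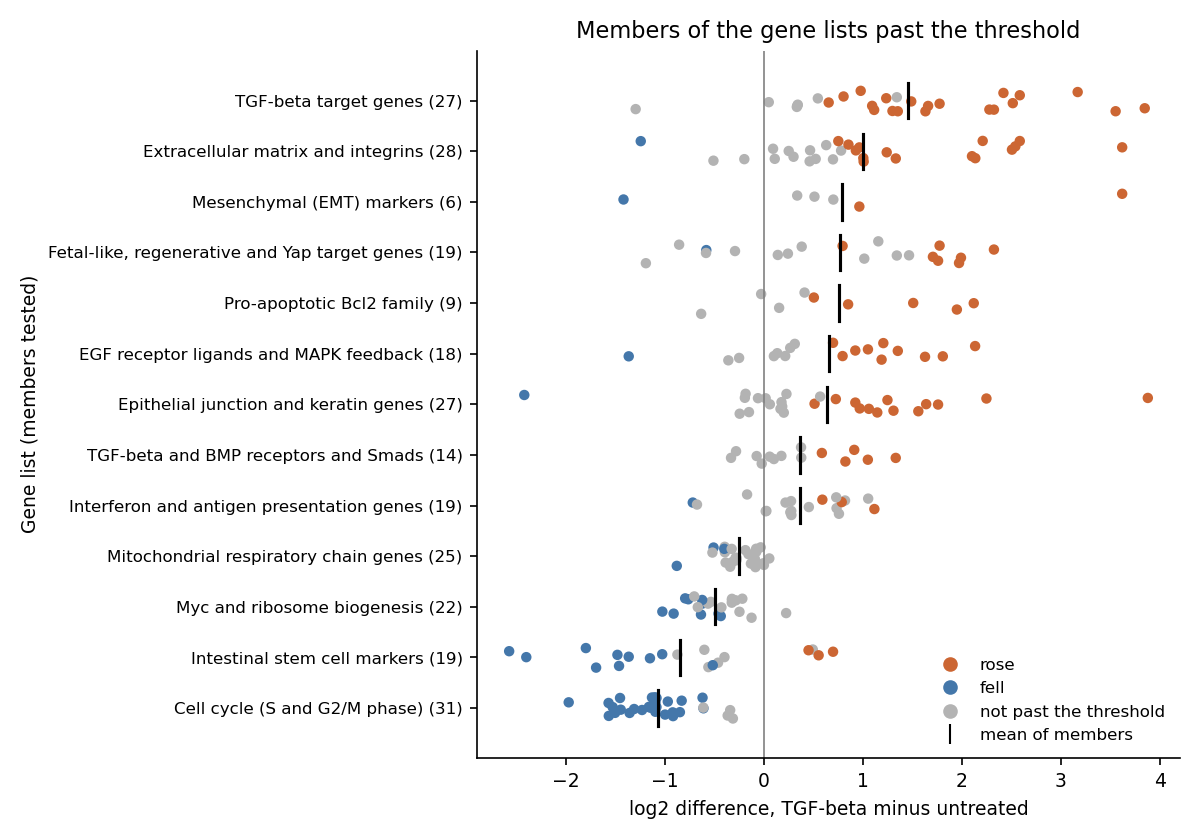
Log2 difference, TGF-beta minus untreated (horizontal axis), of each tested member of the 13 gene lists that passed the camera test at the preset correlation, with the number of members tested beside each name; orange points rose, blue points fell, grey points did not pass, and black lines are list means. The list means run from -1.07 for the cell cycle list to +1.46 for the TGF-beta target list.

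Genes of the EGF receptor pathway were higher with TGF-beta, although growth factors had been withdrawn. Egfr itself rose 4.39-fold (adjusted p = 0.00031), the feedback inhibitor Errfi1 3.50-fold and the immediate early gene Fos 3.09-fold, and Lrig1, a negative regulator of EGF receptors, fell 2.58-fold. In all, 10 of 18 rose and 1 fell, the same counts as when adjusted over the list alone (mean +0.66; camera, adjusted p = 5.5e-05, and adjusted p = 0.334 with an estimated correlation). Fetal-like, regenerative and Yap target genes had 7 of 19 higher and 1, Gja1 (-0.58, 3 TGF-beta arrays), lower (9 and 1 adjusted over the list alone, 11 and 4 with the replicate block). Anxa5 rose 3.97-fold, Il1rn 3.92-fold, Ccn1 3.42-fold and Krt7 3.38-fold. This list's mean was +0.77 (SD over members 1.09), with +0.56 in replicates 1 and 4 and +0.97 in replicates 2 and 3 (camera, adjusted p = 0.0017, and adjusted p = 0.625 with an estimated correlation). It missed the threshold when members shared with other lists were left out (adjusted p = 0.122).

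Stress and immune genes moved less evenly. Of 21 p53 targets, Plk2 (+1.41), Ddit4 (+1.04) and Pmaip1 rose and Gtse1 (-1.30) and Sesn1 (-0.77) fell; the mean was +0.02, the median -0.03, and the list did not pass (camera, upward, adjusted p = 0.668); with the replicate block 4 rose and 5 fell. Ddit4 missed the threshold without untreated replicates 2 or 3 or TGF-beta replicates 1, 3 or 4 (adjusted p from 0.053 to 0.063), and Sesn1 without the same samples (adjusted p from 0.054 to 0.080). Of 23 unfolded protein and stress response genes, 4 fell and 0 rose (limma; 1 higher and 5 lower at an unadjusted p under 0.05), with the asparagine synthetase gene Asns (-0.68) at the smallest adjusted p (0.0058), and the list did not pass (camera, adjusted p = 0.256); with the replicate block 7 fell. Trib3 (-0.69) and Ern2 (-0.91) missed the threshold without untreated replicates 1, 2 or 3 or TGF-beta replicates 1, 3 or 4 (adjusted p from 0.054 to 0.118), and Chac1 (-1.27) without untreated replicate 4 or any 1 of the TGF-beta replicates (adjusted p from 0.055 to 0.070). Of 19 interferon and antigen presentation genes, Irf1 (+0.79), Rsad2 (+1.12, 1 untreated array) and H2-T23 (+0.59) rose and Ifit2 (-0.72, 1 TGF-beta array) fell; with the replicate block 7 rose and 1 fell. The list mean was +0.36 (camera, adjusted p = 0.022, and adjusted p = 0.625 with an estimated correlation) and missed the threshold with array weights (0.125) and without untreated replicates 1 or 4 or TGF-beta replicates 2 or 3 (adjusted p from 0.054 to 0.083). Rsad2 missed it without untreated replicates 1, 3 or 4 or TGF-beta replicates 2 or 3 (adjusted p from 0.053 to 0.088), and H2-T23 without untreated replicates 1, 2 or 4 or TGF-beta replicates 2, 3 or 4 (adjusted p from 0.075 to 0.100). Rsad2 was only +0.35 without background correction (limma, adjusted p = 0.078) and +0.385 on the authors' table (0.073). Among 15 chemokine, cytokine and antimicrobial genes, Cxcl16 rose 4.34-fold, Tnfaip3 rose by 1.08 (3 untreated arrays) and Lcn2 was at least 1.40-fold higher, while Pigr, Reg3b and Reg3g (3.92-fold, 1 TGF-beta array) fell (4 and 5 adjusted over the list alone, 6 and 7 with the replicate block). The list mean was -0.55 and the list did not pass (camera, adjusted p = 0.954), except on set means (0.014).

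Metabolic and general genes gave small values. Of 25 respiratory chain genes, Uqcrq (-0.88), Ndufv2 (-0.51) and Ndufv1 (-0.40) fell and 0 rose (limma; 6 lower and 0 higher at an unadjusted p under 0.05); adjusted over the list alone 1 fell, and with the replicate block 5 fell. The list mean was -0.25 (camera, adjusted p = 0.019, and adjusted p = 0.625 with an estimated correlation), and it missed the threshold within replicates 2 and 3 (0.065), on set means (0.102), without untreated replicate 3 and without TGF-beta replicate 1 (adjusted p from 0.058 to 0.066). Ndufv1 missed it without any 1 of the 8 samples (adjusted p from 0.051 to 0.112), and Ndufv2 without untreated replicates 2, 3 or 4 or TGF-beta replicates 1 or 4 (adjusted p from 0.051 to 0.085). Of 21 glycolysis and hypoxia genes, Egln3 (+0.72) and Slc16a3 (+0.70) rose and 0 fell (limma; 5 higher and 0 lower at an unadjusted p under 0.05; camera, adjusted p = 0.114); with the replicate block 4 rose and 1 fell. The list passed within replicates 1 and 4 (0.030) and without untreated replicate 3 (0.028). Slc16a3 missed the threshold without any 1 of the samples but TGF-beta replicate 4 (adjusted p from 0.052 to 0.089). It was only +0.23 without background correction (limma, adjusted p = 0.069) and +0.25 on the authors' table (0.063). Egln3 was +0.36 with averaged probes (limma, adjusted p = 0.102) and +0.61 with median scaling (0.075). Of 21 cholesterol and fatty acid synthesis genes, Stard4 fell (-0.66, adjusted p = 0.0082) and 0 rose (limma; 1 higher and 3 lower at an unadjusted p under 0.05, 2 and 3 with the replicate block). Of 10 housekeeping genes, Actb (+0.84) and Ywhaz (+0.50) rose and 0 fell (limma; 1 lower at an unadjusted p under 0.05, 2 with the replicate block). Actb missed the threshold when a gene's probes were averaged (adjusted p = 0.989), and Ywhaz without untreated replicates 1, 2 or 3 or TGF-beta replicates 1, 3 or 4 (adjusted p from 0.065 to 0.100). Of 19 ribosomal protein genes, 0 passed (limma; 2 lower at an unadjusted p under 0.05 and with the replicate block), and neither these, nor the cholesterol list, nor the housekeeping list passed as lists (camera, adjusted p = 0.254, 0.582 and 0.587).

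Markers of cells outside the epithelium were mostly below detection. Of 12 fibroblast, 8 smooth muscle and 10 endothelial markers, 1 each was tested, and 0 of these 3 passed (limma; 1 at an unadjusted p under 0.05, in the endothelial list). Of 18 immune cell markers, 4 were tested and 0 passed (1 at an unadjusted p under 0.05; camera, adjusted p = 0.254); with the replicate block 2 rose. Of 19 tuft cell markers, 3 were tested and 0 passed (0 at an unadjusted p under 0.05). Among the 3 tested Id genes, targets of BMP signalling, 0 passed (limma; Id2, at -0.84, was under 0.05 unadjusted, adjusted over the list alone and with the replicate block), with Id1 at +0.31 (SE 0.193, adjusted p = 0.306) and Id3 at -0.68 (SE 0.456, adjusted p = 0.358, detected on 3 arrays of each group). With the replicate block the adjusted p of Id3 was 0.0077. In all, 17 of the 20 key genes were tested and 9 passed.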

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

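The comparison of the TGF-beta effect between the sets of replicates was chosen after the sets had been seen, as were the tests on it below. In 5 of 238 groups of 4 values (2.10%), a sample lay far from the other 3, where chance gives about 1 in 20 for values from a single normal distribution. Where the sets differ, the 4 values fall into pairs and a lone sample is flagged less easily. The rate therefore does not show that such samples were rarer than chance. Aldh1a1 was 8.48 in untreated replicate 4 (others 7.615 to 7.746), and Cdkn2c was 6.49 in TGF-beta replicate 1 (others 5.332 to 5.464). Vim was 7.82 in TGF-beta replicate 3 (others 8.357 to 8.467), Lamb3 was 11.2 in TGF-beta replicate 2 (others 11.68 to 11.72), and Irf1 was 9.26 in TGF-beta replicate 4 (others 9.698 to 9.773).

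The effect of TGF-beta differed between replicates 2 and 3 and replicates 1 and 4 for 5 lists at the preset correlation, given as the first set's mean minus the second's. The pro-apoptotic Bcl2 list rose more in replicates 2 and 3 (+0.35, adjusted p = 0.0455), as did the fetal-like and Yap list (+0.41, adjusted p = 0.00527). The cell cycle list (-0.25, adjusted p = 0.00607), the Wnt target list (-0.41, adjusted p = 0.00365) and the stem cell list (-0.36, adjusted p = 0.0204) had lower means there. With an estimated correlation the adjusted p of these 5 lay between 0.547 and 0.618. Of single genes, Dbp, a clock-controlled transcription factor, gave -0.33 in replicates 1 and 4 and -2.78 in replicates 2 and 3 (difference -2.45, SE 0.27, adjusted p = 0.028).

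The larger falls of the cell cycle and Wnt target lists in replicates 2 and 3 were weighed against low signal in TGF-beta replicate 2, the array with the fewest detected probes. Without that array the differences were -0.21 (adjusted p = 0.049) and -0.53 (adjusted p = 0.00034), which argues against it, although TGF-beta replicate 3 then stands alone and is assumed to vary like the other groups. Among members at 7 or above on all arrays they were -0.25 (20 members) and -0.47 (13 members), which argues against values near the background. In all, 24 of 31 cell cycle and 17 of 22 Wnt target members had a lower effect in replicates 2 and 3. The labels name no difference between the sets, so no biological explanation was tested, and correlation between genes of a list stays open.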

How the results depend on the processing

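The fits with the set as a block, within a set and on set means, and the estimated correlation with the set as a block, were chosen after the result was seen. Apart from the estimated correlation, genes named by the rule and past the threshold kept direction and call in 2166 of 2350 comparisons. They lost the call in 184, with 0 reversed. Genes named outside the rule are not in these counts nor, apart from the replicate block, in the calls lost or gained below. Lists past the threshold kept the call in 271 of 298 and lost it in 27. Of the comparisons for genes not past it, 148 of 174 stayed so, 23 passed and 3 reversed; for lists, 362 of 412 stayed so, 12 passed and 38 reversed. The replicate block gave 4546 probes (2750 without it), 1302 genes higher and 1566 lower. Among named results it changed the calls of Cdkn1a, Ascl2, Id3, Id2, Muc2, Tgfbi and the goblet list and no other. The set block gave 4583 probes, 1308 genes higher and 1580 lower. An adjusted p under 0.01 left 1270 probes, 475 genes higher and 361 lower, and a 2-fold minimum left 1043, 429 and 273. Median scaling gave 495 genes higher. With an estimated correlation, 2 lists were higher and 0 lower, and 3 and 0 with the set block added, which adds the extracellular matrix list, against 9 and 4. Without 1 sample in turn, genes lower ranged from 572 (without untreated replicate 1) to 805 (without TGF-beta replicate 1); fewer samples were fitted. Of named genes, median scaling ended the calls of Bmpr2, Bcl2l1, Tradd, Dapk2, Cdkn2a, Hey1, Ddit4, Irf1, H2-T23, Egln3, Slc16a3, Ndufv1, Ndufv2, Ywhaz and Ctnnb1, and no filter those of Slc27a2, Olfm4, Hey1, Vim, Plk2, Ddit4, Sesn1, Chac1, Trib3, Ern2, Rsad2, H2-T23 and Slc16a3. No background correction ended those of Smad6, Cdkn2a, Hey1, Chac1, Ern2, Rsad2 and Slc16a3, the authors' table the same but Chac1, averaged probes those of Ppan, Ifit2, Egln3 and Actb, cyclic loess those of Ern2, Ndufv1 and Ndufv2, array weights that of H2-T23, trended and robust variances that of Olfm4, and set means those of Dapk2 and Ndufv1. Within replicates 1 and 4, with 4 samples fitted, Bmpr2, Smad6, Bcl2l1, Dapk2, Cdkn2c, Cdkn2a, Odc1, Ppan, Vil1, Pla2g2a, Sesn1, Trib3, Ern2, Irf1, H2-T23, Stard4, Slc16a3, Ndufv1, Ndufv2 and Ywhaz did not pass, and within replicates 2 and 3 Tradd, Dapk2, Cdkn2a, Notch1, Hey1, Mmp14, Chac1, Trib3, Ern2, Ifit2, H2-T23, Egln3, Ndufv1, Ndufv2, Ywhaz and Fzd7 did not. Calls were gained by Cdkn1a with cyclic loess (adjusted p = 0.048), trended and robust variances (0.042), averaged probes (0.031), the set block (0.030) and set means (0.030), by Ascl2 with median scaling, the stricter filter, trended and robust variances, array weights, averaged probes, the set block, set means and within each set (0.00072 to 0.042), and by Id3 with the set block (0.030), set means (0.0090) and within replicates 2 and 3 (0.039). A fit with the slide as a block was not run, as the files name no slides.

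Every reversed value belongs to a list or gene that did not pass, and the cause was not tested. Without background correction the p53 list was -0.0070 (0.018 as reported) and the Apc and Wnt component list 0.00097 (-0.023). Median scaling gave -0.080 for caspases (0.072), -0.084 for CDK inhibitors (0.049), -0.0012 for enterocyte markers (0.15), -0.125 for p53 targets, -0.082 for cholesterol genes (0.065), -0.121 for housekeeping genes (0.018) and -0.052 for Tgfbr2 (0.057). Cyclic loess gave 0.012 for the Notch list (-0.031) and 0.015 for Apc and Wnt components, the authors' table -0.0061 for p53 targets, and no filter 0.0068 for Apc and Wnt components. Array weights gave -0.41 for enterocyte markers, 0.013 for Notch, -0.018 for cholesterol and -0.017 for housekeeping genes, and averaged probes -0.072 for housekeeping genes. Within replicates 1 and 4, Notch was 0.011, p53 -0.024 and housekeeping -0.049; within replicates 2 and 3, CDK inhibitors were -0.18. Without members of other lists, CDK inhibitors were -0.37, enterocyte markers -0.067 and p53 targets -0.021. Leaving out 1 sample in turn, Tgfbr2 ranged from -0.071 to 0.16, Apc and Wnt components from -0.063 to 0.0099, CDK inhibitors from -0.021 to 0.098, enterocyte markers from -0.24 to 0.56, housekeeping genes from -0.015 to 0.050, Notch from -0.084 to 0.0043 and p53 targets from -0.124 to 0.148. Genes near the lowest detected signals, 5.04 to 5.23, are limited by the background, and the 56 with a bound have no measured fold.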

Other observations

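The sets of replicates, the tests between them, the split counts for probes and genes, and the stratified epithelium tests were chosen only after the results were seen. Replicates 2 and 3 differed from replicates 1 and 4 in both groups, with 816 genes higher and 1016 lower (limma with the group as a block, 4 samples against 4). The 4 samples of a set are 2 replicate numbers, each measured in both groups, and may not be independent. This fit did not link samples of the same number. The counts of genes between the sets may therefore be too high, and the SE and p-values between them, here and below, too small. Besides Xist (+5.09, SE 0.16), genes of absorptive cells were higher in replicates 2 and 3: the apolipoproteins Apoc3 (+4.52, SE 0.19) and Apoa4 (+3.96, SE 0.20), and Adh1 (+4.28, SE 0.17). The Reg family lectin genes Reg1 (+4.03) and Reg3a (+3.92) were higher as well. Lower there were Eif2s3y (-3.77, SE 0.13), S100a7a (-2.92), Sema7a (-2.79) and Cnfn (-2.72). Differentiation lists were higher in replicates 2 and 3 by means of +0.97 for enteroendocrine, +0.77 for goblet and +0.46 for Paneth cell markers (camera at the preset correlation, adjusted p = 7.2e-06, 0.00013 and 0.0057), and the fetal-like and Yap list was lower (-0.96, adjusted p = 3.5e-08). Of the 1832 genes, 341 were also past the threshold for TGF-beta, where independent lists would share 356. The TGF-beta calls came from the fit without a set block, where a difference between sets adds to a gene's spread. This overlap therefore cannot show whether the 2 groups of genes are independent. The TGF-beta effect differed between the sets for 1 gene (limma). At an unadjusted p under 0.05 it differed for 1529 of 15573 probes, a larger share than the 0.05 that chance gives. With 2 samples per set and group, differences can be missed, and 72.5% of simulated log2 differences of 2 were recovered.

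For this division, genes of the sex chromosomes alone were argued against, since 2.13% of its genes lie on X or Y, against 2.74% of tested genes. The number of detected probes was argued against by a mean difference of -128.75 with overlapping ranges (15281 to 16582 and 14554 to 16626). RNA quality, labelling and slide were not covered by this test. A larger share of absorptive cells cannot be told apart, because the enterocyte list was higher by +2.17 (adjusted p = 8.3e-19) and the cell cycle list (-0.36, adjusted p = 6.8e-05) and the Myc and ribosome list (-0.24, adjusted p = 0.013) were lower, but the stem cell list (+0.37, adjusted p = 0.015) and the secretory lists were higher too. Intestinal segment of origin cannot be told apart either, because 8 proximal genes had a mean of +2.03 while the 3 distal genes, at 0.23 (SD 1.61), are too few. By Xist and Eif2s3y, replicates 2 and 3 held female cells and replicates 1 and 4 male cells, so the sets came from different animals. Whether sex, donor or culture batch, none of which the labels give, accounts for the other genes cannot be told apart and was not tested.

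Of genes known from stratified epithelium, 4 that were picked for their rise with TGF-beta were Sfn (+3.61), Anxa8 (+3.55, 3 untreated arrays), Krt14 (+3.24, adjusted p = 0.015, 2 untreated arrays) and Sprr1a (+3.03, 2 untreated arrays). Of 31 squamous markers written, 16 were below the detection filter. Among the 11 others tested, Ivl (2.83-fold, 1 untreated array), Pkp1 (2.82-fold), Ly6d (+1.44) and Lgals7 (at least 1.30-fold, 0 untreated arrays) rose, 0 fell and 7 did not pass, among them Krt4 (-1.11) and Tgm1 (-0.31). Against cells of a stratified epithelium in the treated samples stood Krt5, the partner of Krt14, at -0.07 and detected on 0 arrays. Krt6a, Krt13, Trp63 and Dsg3 were also detected on 0 arrays, although Krt6b and Krt16 were detected on 3 TGF-beta arrays and 0 untreated ones. Lor, another of the markers, was detected on all arrays, at 7.75 in untreated and 8.37 in TGF-beta samples. Probe positions were not checked, so undetected probes do not show silent genes and cannot decide whether such cells were present. Expression by the organoid cells themselves stays open and was not tested.

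Of the 35 ways to split the 8 arrays into 4 and 4, only 1, the real split, gave as many probes as its 2750, and the highest other count was 759, for the split by sets. For genes 1 of 35 gave as many as 1762, with 492 the next. For lists 4 of 35 gave as many as 13, the highest other being 14. The other splits that did so, such as untreated 1, 2 and 3 with TGF-beta 2, kept most arrays of a group together. They still carried part of the TGF-beta effect, so the number of lists cannot test chance, which is not excluded for it. Among the 8 splits that part all 4 numbered pairs, the highest other counts were 0 probes and 11 lists. If the numbers pair the samples, only these splits are a like reference for the real one. The real split can then be at best 1 in 8, which is too few to exclude chance for probes, genes or lists.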
